A study of Mus musculus with 4 samples.

How the data were processed

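Germline stem cell-like cells (GSCLCs) were profiled in 4 samples of 1 group, named sample 1 to sample 4 here after the numbers in the labels. Per the labels' protocols, the cells were grown from reconstituted testes, in which germ cells made from mouse embryonic stem cells had been combined with fetal testis somatic cells. Per the labels, 15000 sorted cells were used for each sample, unmethylated lambda phage DNA was added before bisulfite treatment, and libraries were made by post-bisulfite adaptor tagging, a method that adds adaptors after the bisulfite step. What the 4 numbers stand for (lines, cultures or preparations) is not given in the sources used here, so every spread below measures differences between these samples, which may be technical.

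The deposited files hold, for each cytosine of each CpG, the count of methylated and the count of unmethylated calls by strand, as the authors' pipeline wrote them, with no normalisation. Per the submitters' processing notes, the tools were Trim Galore 0.4.1, cutadapt 1.9.1, Bowtie2 2.3.4.1 and Bismark 0.22.1, and the build was GRCm38.p6. Trimming lengths, removal of duplicate reads and the conversion rate are not given in the sources used here. Duplicate reads left in would make the counting intervals too narrow, and unconverted cytosines would raise every level. Lambda phage calls were not analysed here. All 4 files listed the same 21865266 CpGs on 22 sequences.

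Both strands of a CpG were added together. Levels are methylated calls over all calls. For genome-wide and feature levels, CpGs with 5 to 200 calls were averaged with equal weight; the upper limit removes collapsed repeats, where 3178 to 3899 CpGs per sample held 11.8% to 12.2% of all calls. Exact 95% binomial intervals (Clopper-Pearson) treat all calls as independent, but reads without molecular identifiers are not independent molecules. The variance of differences between the strands of a sample was 3.26 times the binomial value in promoters. In 10 kb windows it was 4.01 times that value. Calls thus vary more than the intervals allow, and all such intervals below are too narrow.

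Gene positions came from a RefSeq gene table of the same build with 49997 genes, which gives gene ends but neither strand nor exons; no genome sequence was used here. The promoter window of each of 21887 protein-coding genes was therefore placed at the gene end with more CpGs, from 1000 bp outside to 500 bp inside the gene. Among 39 Hox genes, whose strand is known from textbooks, the start was chosen for 30, and for 22 of 22 where the chosen end had at least 2 times the CpGs of the other end. An end with that margin is called a clear end below. None of the 22 windows is of the low-CpG class defined next, so clear ends of that class were not checked. Other genes were not checked in this way either. A window without a clear end is not known to be the start of its gene, and a clear end does not secure the start, as Dnmt1 below shows. The word promoter below stands for such a window. Windows were classed by CpG number into low (up to 24), intermediate (up to 66) and high. CpG-dense stretches, a stand-in for CpG islands, were merged 500 bp windows with 25 or more CpGs. Comparisons of exons with introns and of repeats with other sequence, and the choice of the most upstream start, were not run for want of the annotation. Windows needed 5 covered CpGs and 20 calls in every sample.

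Maternally methylated imprinted regions were windows 1000 bp either side of the more CpG-rich end of 15 genes. Paternally methylated regions were 2 to 4 kb upstream of H19, 12 to 14 kb upstream of Meg3 and 28 to 32 kb upstream of Rasgrf1, with strands from textbook knowledge. The table's ends of Snrpn, Mest and Impact lie away from their CpG-rich starts, so the Snurf end and the most CpG-rich 2 kb inside Mest and Impact were added after seeing the data.

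Paired differences between features were tested with exact two-sided sign-flip permutation tests, which cannot go below p = 0.125 with 4 samples. Paternal and maternal regions were compared by an exact two-sided permutation of regions. Each of 16 gene lists was compared with 10000 random lists with the same numbers of windows per CpG class (two-sided permutation test across genes, Benjamini-Hochberg over lists). Differences between samples were tested with the moderated F test of limma 3.58.1 in R 4.3.3. It was run on arcsine square root levels of the forward and reverse strand of each sample as technical repeats, weighted by the square root of the calls. A promoter needed 10 and a 10 kb window 50 calls on each strand, a Benjamini-Hochberg adjusted p under 0.05 and a range of at least 20 percentage points. These p-values compare the 4 libraries, not conditions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.

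Both tests were tested on simulated data. In 20547 simulated promoters, 70.0% of those shifted by 40 points in 1 sample were called, 22.0% of those shifted by 30 points and 2.0% of those shifted by 20 points, with 4 of 20347 unchanged promoters called. In 40000 simulated 10 kb windows the shares were 96.0%, 90.0% and 50.0%, with 0 of 39800 unchanged windows called by limma (4 past the adjusted p alone). The list test on 20646 windows gave p under 0.05 for 4 of 100 random lists and for 100 of 100 intermediate-CpG lists raised by 20 points.

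Tests, lists, alternatives and the rule for named genes were set before the data were examined, except where stated. The comparison of gene bodies with intergenic sequence was not in that plan, and it is included in the adjustment over features. The rule takes every imprinted region and the 2 highest and 2 lowest promoters of each list, except lists given by a name pattern. It adds the 10 promoters of largest range among those differing between samples whose highest and lowest samples agree on both strands. It further takes the 10 highest high-CpG promoters at 80% or more in every sample, the 5 lowest low-CpG promoters at 20% or less in every sample, and the reporter genes Prdm1, Dppa3 and Ddx4. Not every gene the rule takes is reported here. The gene Dnmt3c of the methylation list was not matched in the table. Alternatives were coverage limits, pooled reads, single strands, 500 bp windows, other bounds, scales and weights, and leaving out each sample.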

Results

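The methylome of mouse GSCLCs, cultured germ cells with features of spermatogonial stem cells, was measured in 4 samples. The files held 502934952, 424174692, 509103675 and 498940231 CpG calls in samples 1 to 4 outside the mitochondrial genome. Between 91.2% and 91.4% of listed CpGs had a call, and the median autosomal CpG had 21, 17, 21 and 21 calls. All samples belong to 1 group, so the comparisons are between parts of the genome within samples, and between the samples themselves.

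The autosomes of GSCLCs were highly methylated. The mean CpG level was 80.5% ± 1.88 (SD, n = 4), with 79.99%, 83.2%, 78.9% and 80.1% in samples 1 to 4. Of the CpGs, 76.6% ± 3.82 were at 80% or more and 12.5% ± 1.12 at 20% or less (SD, n = 4). The X chromosome, single-copy in male cells, was lower than the autosomes in 4 of 4 samples, at 75.4% ± 3.16, a difference of -5.16 ± 1.27 points (SD, n = 4; exact sign-flip test p = 0.125, the smallest possible). Chromosome 7 was the least methylated autosome at 77.1% ± 1.74 and chromosome 18 the most methylated at 82.8% ± 1.83 (SD, n = 4). The Y chromosome read 33.6% ± 9.44 (SD, n = 4), with 47.3% in sample 2 and 27.1% to 32.2% in the others. The median Y CpG had 0 calls in every sample, and 37632 to 43516 Y CpGs per sample had enough calls. These Y values therefore cover only part of the chromosome. Pooled over calls, the exact 95% interval of each autosomal level was narrower than 0.01 points, far below the spread between samples.

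Averaged over CpGs, promoter windows and CpG-dense stretches were the least methylated of the features compared. Each CpG counts equally in these means, so CpG-rich windows dominate that of promoters. The windows were also placed at the gene end with more CpGs, which favours a low level. Promoter windows averaged 13.1% ± 0.742 against 84.1% ± 2.62 between genes, a difference of -71.0 ± 2.17 points (SD, n = 4). CpG-dense stretches averaged 11.3% ± 1.26 against 87.2% ± 1.95 outside them, a difference of -76.0 ± 1.13 points (SD, n = 4). Both differences held in 4 of 4 samples (exact sign-flip test p = 0.125, the smallest possible, adjusted p = 0.188). Gene bodies, at 84.5% ± 1.48, differed from intergenic sequence by 0.423 ± 1.42 points (SD, n = 4), higher in 3 of 4 samples, which is within the spread between samples (exact sign-flip test p = 0.625). This difference was 0.0938, 1.102, 0.393 and 0.102 points without samples 1, 2, 3 and 4 in turn, and 0.0981 ± 1.55 points with samples 1 and 4 counted as 1 (SD, n = 3). CpGs in 500 bp intervals holding 5 CpGs, centred on the CpG itself, read 88.6% to 93.2% in the samples, and those in intervals with 60 or more CpGs read 0.793% to 0.814%.

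**Figure D1:**
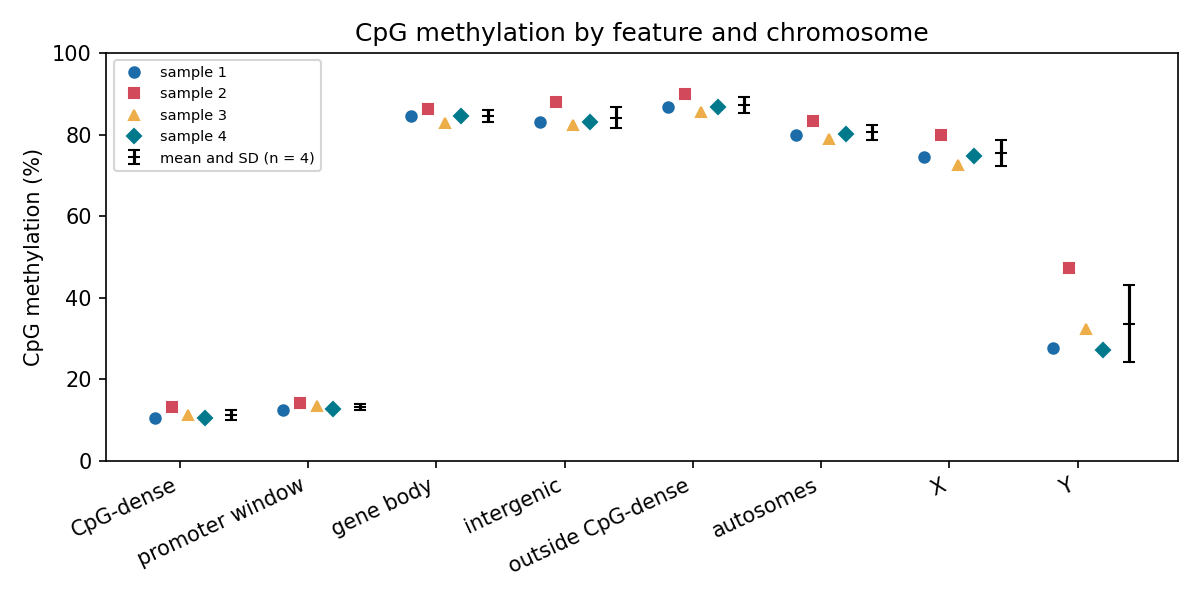
CpG methylation (%, vertical axis) of genomic features and chromosomes, with a coloured symbol for each of the 4 samples and a black bar for mean and SD. Promoter windows and CpG-dense stretches sit near 13.1% and 11.3%, gene bodies and intergenic sequence near 84.5% and 84.1%.

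**Figure D2:**
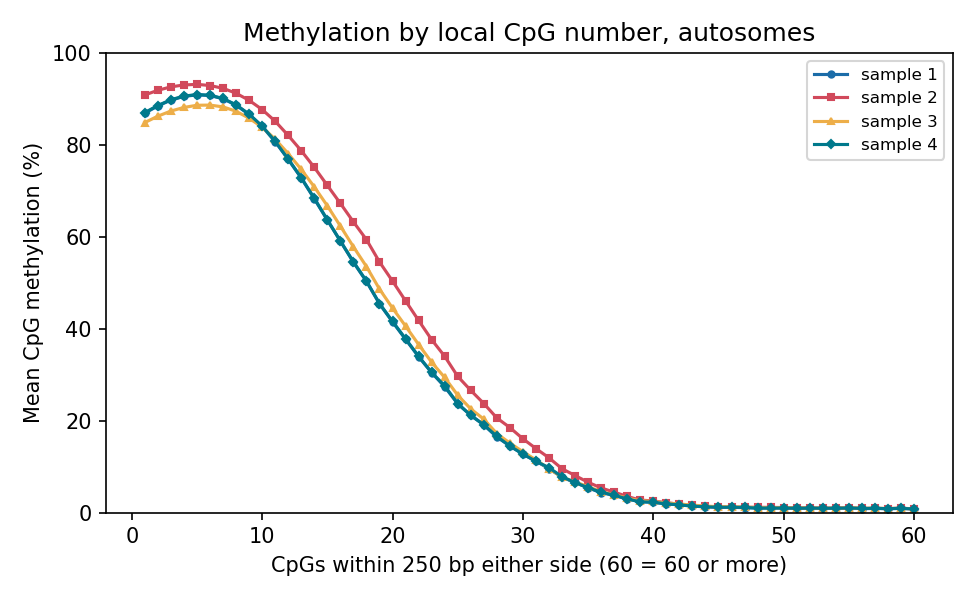
Mean methylation of autosomal CpGs (%, vertical axis) by the number of CpGs within 250 bp either side (horizontal axis), with a coloured line for each sample. The lines rise slightly at first, read 88.6% to 93.2% at 5 CpGs and 0.814% or less at 60 or more, and sample 2 lies highest at 20 CpGs with 50.4%.

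Promoter methylation followed CpG number. Averaged over windows and not over CpGs, high-CpG windows read 2.39% ± 0.289, intermediate windows 21.1% ± 1.75 and low-CpG windows 78.9% ± 2.37 (SD, n = 4). The high-CpG minus low-CpG difference was -76.5 ± 2.16 points and was negative in 4 of 4 samples (SD, n = 4; exact sign-flip test p = 0.125, the smallest possible). Of 7184 high-CpG windows, 7132 were at 20% or less in every sample and 0 were at 80% or more. Of 7271 intermediate windows, 4976 were at 20% or less and 668 at 80% or more. Of 6191 low-CpG windows, 202 were at 20% or less and 3683 at 80% or more. The lowest of those 202 were the predicted genes Gm10323 and Gm44, Ccdc89, and the zinc finger genes Zfp937 and Zfp120, at 0.610% to 0.799%. Only Ccdc89 and Zfp937 of these have a clear end, so the other windows are not known to be the start of the gene. The value of Gm10323 rests on few calls, and 0 methylated among 54, 41 and 33 calls in samples 1, 2 and 4 allow up to 5.56%, 7.32% and 9.09%. Restricting to genes with a clear end, an alternative chosen after seeing the data, left 1068 windows at 80% or more in place of 4351. Fewer windows entered this count. In the low-CpG class 861 of 1800 (47.8%) were at 80% or more, against 3683 of 6191 (59.5%) before. In the intermediate class 207 of 5113 (4.05%) were, against 668 of 7271 (9.19%).

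Paternally methylated imprinted regions were methylated and maternally methylated ones were largely not. In germ cells of the male line, imprints are erased and then set anew in the paternal pattern. The 3 paternal regions averaged 83.0% and the 15 maternal regions 15.1%, a difference of 67.9 points (exact permutation test over 816 splits of the regions, p = 0.00368). It ranged from 61.3 to 77.2 points between the samples. The control region upstream of H19, the noncoding gene next to Igf2 (chromosome 7, 142580146 to 142582146), read 95.9% ± 3.01, and the intergenic region upstream of Meg3, a maternally expressed noncoding gene (chromosome 12, 109526996 to 109528996), read 96.2% ± 1.19 (SD, n = 4). The region upstream of Rasgrf1, a guanine nucleotide exchange factor for Ras (chromosome 9, 89877508 to 89881508), read 56.9% ± 18.5 (SD, n = 4). It was at 84.0% in sample 2 (exact 95% interval 81.5% to 86.4%) and at 53.7%, 44.5% and 45.6% in samples 1, 3 and 4.

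Of the 15 maternal regions, 11 averaged 10% or less. Peg3 (1.25%), Nespas (1.09%), Peg13 (1.48%), Plagl1 (1.99%), Mcts2 (2.34%), Zrsr1 (3.02%) and Nnat (3.43%) were the lowest, followed by Nap1l5 (4.98%), Kcnq1ot1 (5.32%), Airn (5.37%) and Slc38a4, an amino acid transporter (7.85%). Peg10, a gene derived from a retrotransposon and needed for the placenta (chromosome 6, 4746306 to 4748306, 128 CpGs), read 35.1%, 5.02%, 39.6% and 36.9% in samples 1 to 4. The exact 95% intervals were 4.196% to 5.96% in sample 2 and 33.4% to 36.8% in sample 1. The windows of Snrpn (77.1%, 11 CpGs), Impact (64.8%, 22 CpGs) and Mest (17.4%, 50 CpGs) lay away from CpG-rich starts. At the CpG-rich sites, added after seeing the data, Impact read 1.67%, Mest 1.72% and Snurf, which shares the Snrpn promoter, 6.49% ± 9.85 (SD, n = 4). Snurf (chromosome 7, 60004199 to 60006199, 44 CpGs) was at 21.2% in sample 3 (exact 95% interval 18.5% to 24.0%) and at 3.29%, 0.6504% and 0.851% in samples 1, 2 and 4. With those sites the maternal mean was 5.14% and the difference 77.9 points.

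**Figure D3:**
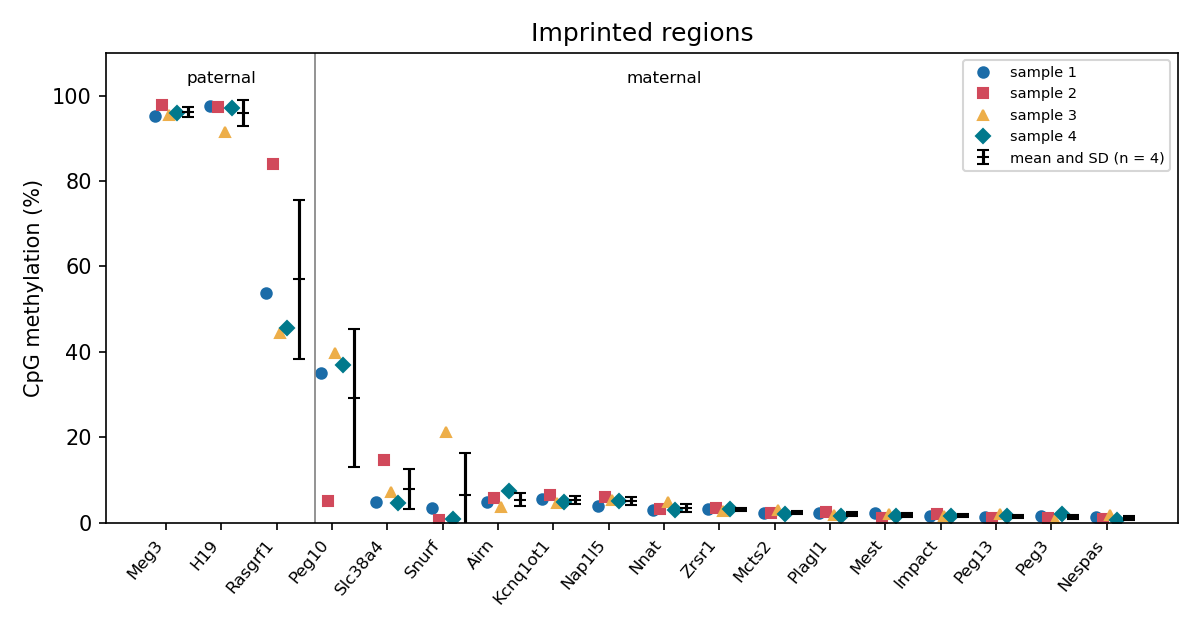
Methylation (%, vertical axis) of 3 paternal and 15 maternal imprinted regions, with a coloured symbol per sample and a black bar for mean and SD (n = 4), using the CpG-rich sites of Snurf, Mest and Impact. H19 and Meg3 lie above 91% in all samples, while Rasgrf1 and Peg10 part sample 2 from the others, at 84.0% and 5.02%.

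Promoters of germ-cell genes were unmethylated as a rule. Of 33 germline genes, active in meiosis and in piRNA silencing of transposons, 25 were at 20% or less in every sample. Tdrkh (1.04%) and Sycp3, a component of the synaptonemal complex (1.32%), were lowest, and Dmrtb1 (94.6%) and Piwil2 (96.4%) were highest. Of 24 spermatogonial stem cell genes, 22 were at 20% or less in every sample, with Lhx1 (0.520%) and Taf4b (0.682%) lowest and Nanos2 (67.5% ± 7.30; SD, n = 4) and Nanos3 (96.7%) highest. Nanos2 encodes an RNA-binding protein of male germ cells, and its window has 22 CpGs. In the 14 genes of differentiating spermatogonia and meiotic entry, 11 were at 20% or less, including the recombination factor Prdm9 (1.38%) and Dmrt1 (1.39%). Stra8, the retinoic acid-induced gene of meiotic entry, read 68.9% ± 18.2 (SD, n = 4) and Spo11, which makes meiotic double-strand breaks, 96.1%. Of Dmrt1, Dmrtb1, Piwil2, Nanos2, Nanos3, Stra8 and Spo11 only Piwil2 has a clear end. The other windows are not known to be the start of the gene. The Piwil2 window is of the low-CpG class, where clear ends were not checked. None of these lists stood apart from CpG-matched random lists (permutation tests, adjusted p = 0.648, 0.390 and 0.758).

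Among the reporter genes, the Prdm1 promoter, of a transcription factor of primordial germ cells (chromosome 10, 44528058 to 44529558), read 1.68% ± 0.308 (SD, n = 4). The promoter of Ddx4, a germ-cell RNA helicase (chromosome 13, 112652133 to 112653633), read 10.5% ± 6.62, and that of Dppa3 (chromosome 6, 122625424 to 122626924) 37.2% ± 5.24 (SD, n = 4). The cells carry transgenes of all 3 genes, and reads from promoter copies in those transgenes are counted at the same sites. Calls per CpG were 18.2 to 19.7 times the median autosomal depth at Dppa3, 5.70 to 5.89 times at Prdm1 and 2.67 to 2.90 times at Ddx4, against 1.15 to 1.19 times at the median intermediate window. Most calls at these sites therefore exceed the depth of a single-copy locus, and the levels are not those of the native genes alone.

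Spermatid genes were the list with the highest methylation relative to windows matched on CpG class. Their median promoter level was 92.9% against 23.9% in random lists (permutation test, adjusted p = 0.00480), and 11 of 20 were at 80% or more in every sample. The 10 intermediate windows of the list held 27 to 47 CpGs, against a class median of 46. The test therefore does not separate the list from CpG number within that class. Prm1, Prm2, Prm3 and Tnp2 are also neighbours on chromosome 16, so they are not independent. Catsper1, a sperm calcium channel (97.4%), and the kinase Tssk1 (97.0%) were highest, and Gapdhs, the sperm-specific glycolytic enzyme (1.29%), and Spaca1 (3.54%) were lowest. Only 6 of the 20 genes have a clear end, and the strands of the genes, Gapdhs included, were not checked. Those 6 had a median of 6.77% against 7.50% in random lists (adjusted p = 0.895), so the call ended in this alternative, chosen after seeing the data. Olfactory and vomeronasal receptor genes, most of them in low-CpG windows, had a median of 86.5% against 91.5% in random lists (1179 genes; adjusted p = 0.00160, from the smallest permutation p possible, 0.0001). With clear ends only, the receptor median was 83.1% against 84.1% (adjusted p = 0.895), so this call ended too. The mean of the full list did not differ from random lists (adjusted p = 0.389), and without matching on CpG class the list lay above random lists.

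The other 11 lists did not stand apart after adjustment. Pluripotency genes had a median of 10.9% against 4.92% (permutation test, adjusted p = 0.138), with Klf4 (0.827%) and Sox2 (0.899%) lowest and Esrrb (92.3%) and the Nodal antagonist Lefty1 (95.8%) highest. Primordial germ cell genes had a median of 16.6% against 5.62% (permutation test, adjusted p = 0.122), with Nanos1 (1.08%) and Prdm1 (1.68%) lowest and Rhox5 (85.1%) and Ifitm1 (97.4%) highest. With clear ends only, chosen after seeing the data, the median of primordial germ cell genes was 6.38% against 2.86% in random lists (6 genes). That of pluripotency genes was then 5.86% against 2.83% (11 genes). Markers of cells that a sort of testis cultures could carry over were Sertoli genes (10.5%, adjusted p = 0.594), Leydig and peritubular genes (35.0%, adjusted p = 0.884), and fibroblast, endothelial and blood genes (76.4% against 41.1%, adjusted p = 0.263, all permutation tests). With clear ends only, chosen after seeing the data, Sertoli genes had a median of 7.05% against 3.13% in random lists (8 genes). Leydig and peritubular genes then had 17.4% against 7.69% (8 genes), and fibroblast, endothelial and blood genes 4.24% against 3.46% (6 genes). In these lists Dhh (0.992%), Sox9 (1.17%), Myh11 (4.85%), Twist1 (0.851%) and Vim (0.920%) were among the lowest, and Ptgds (96.5%), Gata4 (97.4%), Star (96.8%), Hsd3b1 (97.3%), S100a4 (96.6%) and Pecam1 (96.8%) were highest. Of the highest genes named for these 5 lists only Hsd3b1 has a clear end, and of the lowest only Dhh has none. Windows without a clear end are not known to be the start of the gene. The Hsd3b1 window is of the low-CpG class, where clear ends were not checked.

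Developmental regulators were unmethylated in most cases. Of 39 Hox genes, which set body-axis identity, 30 were at 20% or less in every sample, and the median was 3.08% (adjusted p = 0.648). Hoxc13 (1.02%) and Hoxb8 (1.03%) were lowest and Hoxc4 (92.9%) and Hoxd4 (93.7%) highest. Of 32 lineage transcription factors, 29 were at 20% or less, with a median of 3.63% (adjusted p = 0.390). Irx3 (0.730%) and Six2 (1.04%) were lowest, and the cardiac and limb factor Tbx5 (50.04% ± 9.44; SD, n = 4) and Gata3 (93.2%) highest. Housekeeping genes had a median of 2.06% (adjusted p = 0.594), from Rps29 (0.590%) and Polr2a (0.723%) to Actb (69.7%) and Ywhaz (94.3%). The DNA methylation machinery had a median of 12.2% (adjusted p = 0.594), from Trim28 (0.831%) and Tdg (1.04%) to Dnmt1 (97.2%) and Usp7 (97.8%). With clear ends only, chosen after seeing the data, its median was 5.84% against 2.87% in random lists (9 genes). Of these 8 highest members of the last 4 lists only Dnmt1 and Tbx5 have a clear end. The Dnmt1 window lies at the low-coordinate end of a gene read from the reverse strand, so it is not its start. By textbook strand the windows of Hoxc4 and Hoxd4 lie at the start of the gene. That of Hoxb8 lies at the opposite end, so its level is not that of its promoter. The Irx3 window and the other highest windows without a clear end are not known to be the start. The Rhox cluster on the X chromosome had a median of 12.6% (adjusted p = 0.729). Clustered protocadherins, cell-surface proteins of neurons, had a median of 17.6% (adjusted p = 0.648), which is the level of 1 window shared by 18 genes of the gamma cluster (chromosome 18, 37841363 to 37842873). With overlapping windows counted once, chosen after seeing the data, the median was 23.8% over 40 windows, below the 25.5% of random lists (adjusted p = 0.888). Without sample 2 the median over all 57 genes was 10.2%, also below random lists (adjusted p = 0.648).

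**Figure D4:**
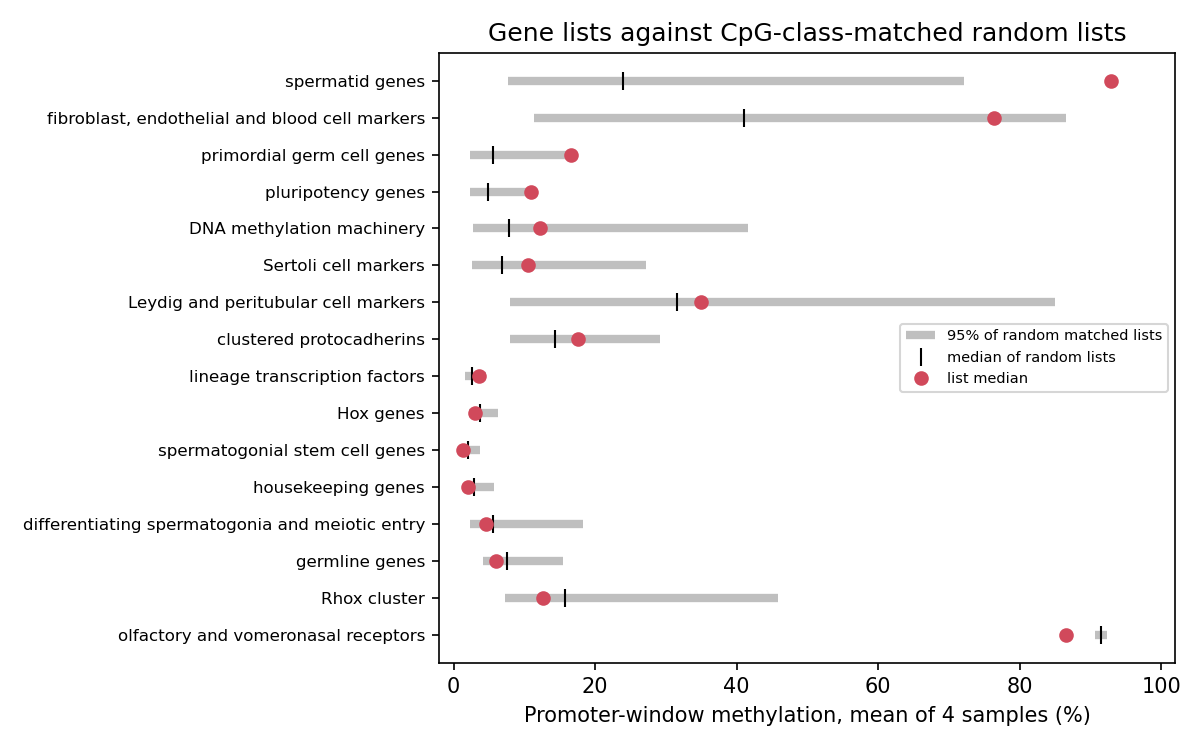
Median promoter-window methylation (%, horizontal axis, mean of 4 samples) of 16 gene lists (red points) beside the median (black tick) and central 95% (grey bar) of 10000 random lists matched on CpG class. Spermatid genes lie at 92.9% and olfactory and vomeronasal receptors at 86.5%, both outside the grey bar, as are primordial germ cell genes at 16.6%, which did not pass adjustment over the lists.

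The samples differed from each other at named promoters by far more than counting error. Of 20547 promoters, 1520 (7.40%) differed between samples in limma's moderated F test with a range of 20 points or more. Sample 2 was highest at 824 of them and sample 3 at 555, and samples 1, 4, 3 and 2 were lowest at 553, 510, 339 and 118. Both strands gave the same highest and lowest sample at 796 of the 1520, and samples 1 and 4 were too alike to order. The largest range was at Eps8l1, an actin regulator (chromosome 7, 4459638 to 4461138), at 75.7%, 96.5%, 2.299% and 80.5% in samples 1 to 4 (limma adjusted p = 3.49e-05). Cndp1, a secreted dipeptidase (chromosome 18, 84609384 to 84610884), read 9.52%, 97.8%, 5.43% and 8.56%, and Acta1, skeletal muscle actin (chromosome 8, 123890758 to 123892258), 20.6%, 92.2%, 14.8% and 21.8%. Spin2d on the X chromosome (73174302 to 73175802) was at 95.1% in sample 2 and 8.02% in sample 3. At Gm1604b, Pate5, Pate6, Gm12886, Gm12888 and Ssxb1, samples 2 and 3 were both above samples 1 and 4, for example 96.0% and 94.4% against 24.2% and 13.3% at Pate5. The strands of the genes named here, Acta1 included, were not checked, so their windows are not known to be the start of the gene. Among promoters with a clear end, an alternative chosen after seeing the data, 622 of 13682 (4.55%) differed. The count fell to 872 without sample 2, to 851 without sample 3 and to 869 on a logit scale.

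Members of the fixed lists were among the promoters that differed; those named here, apart from Stra8, were chosen after their values were seen. They included 5 of 39 Hox genes, such as Hoxb3 (25.8%, 74.7%, 46.7% and 24.6% in samples 1 to 4). Nr5a1, the steroidogenic transcription factor, read 24.4%, 84.6%, 60.9% and 30.5% (limma adjusted p = 0.00139). Stra8 read 82.8%, 71.8%, 42.5% and 78.5% (limma adjusted p = 0.00113), and Nanog 74.4%, 97.0%, 82.3% and 77.8% (limma adjusted p = 0.00277). None of these 4 windows has a clear end, so they are not known to be the start of the gene. Of 40 separate windows of clustered protocadherins 12 differed, 1 of them the window shared by 18 genes, at 6.26%, 39.9%, 19.004% and 5.37%. None of the 24 spermatogonial stem cell genes (0), 20 housekeeping genes (0) or 13 methylation machinery genes (0) was called. At the 7.40% called over all promoters, lists of this size hold few calls. High-CpG windows, which rarely reach a range of 20 points, make up 17 of the 24 and 11 of the 20. The zeros therefore do not set these lists apart. Over all promoters 5779 had an unadjusted limma p under 0.05.

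Differences between samples also ran over large stretches of the genome. Of 251832 windows of 10 kb, 21437 (8.51%) differed with a range of 20 points or more. Sample 2 was highest in 18265 of them and sample 3 in 2303, while sample 3 was lowest in 7434, sample 1 in 7419 and sample 4 in 6253; both strands gave the same highest and lowest sample in 12592. Without sample 2 the count was 6651. The longest run of differing windows covered 530 kb of chromosome 1 (113030001 to 113560000), where the 4 samples averaged 42.3%, 84.9%, 76.9% and 37.5%. The 120 windows beside it averaged 53.5%, 75.3%, 66.6% and 51.8%, so the difference did not end at the edges of the run. In the 15 longest runs samples 2 and 3 were both above samples 1 and 4, and 11 of these runs held no protein-coding gene. Genes of other kinds were not counted. A run of 260 kb on chromosome 16 (59130001 to 59390000) held 11 olfactory receptor genes, at 38.9%, 71.7%, 68.5% and 39.5%. Another run of 260 kb on this chromosome (89020001 to 89280000) held 29 genes, among them keratin-associated protein genes, at 54.4%, 84.8%, 81.4% and 54.8%.

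**Figure D5:**
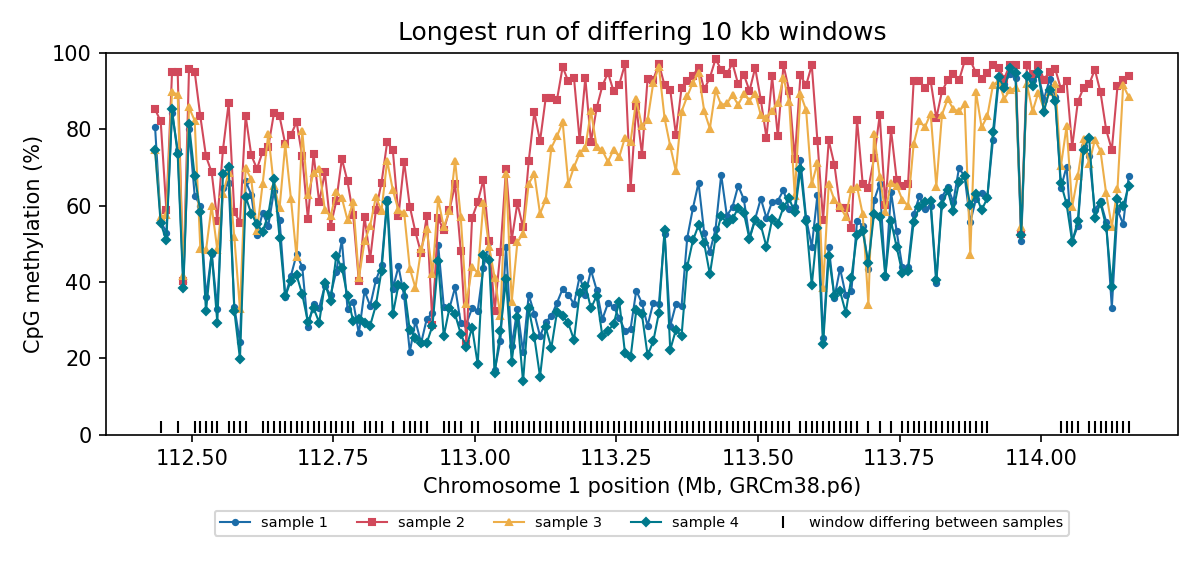
Methylation of 10 kb windows (%, vertical axis) along chromosome 1 (Mb, GRCm38.p6, horizontal axis) around the longest run of differing windows, with a coloured line per sample and black ticks under windows that differed. In the run, samples 1 and 4 average 42.3% and 37.5%, and samples 2 and 3 average 84.9% and 76.9%, and the same order continues at smaller distance in the windows beside it (53.5%, 51.8%, 75.3% and 66.6%).

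Samples 1 and 4 were nearly identical to each other. Between them limma called 0 of 20547 promoters and 0 of 251832 windows in the pairwise comparison, against 761 to 899 promoters and 5665 to 13470 windows in the other pairs. At an unadjusted limma p under 0.05 there were 434 promoters and 3437 windows between samples 1 and 4. Both are smaller shares than the 0.05 that well-calibrated p-values give when nothing differs. The test was thus too strict for this pair, for a reason not tested, and the 0 calls do not show that the samples are equal. Across 20646 promoters, Pearson's r between samples averaged 0.979 over 6 pairs and was 0.998 for samples 1 and 4 (across genes, which are not independent replicates). The files differ in depth and in coverage, so both are kept as samples; with their mean counted as 1 sample, the autosomal level was 80.7% ± 2.27 (SD, n = 3).

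A small part of the genome stayed unmethylated over whole 10 kb windows. Of 237880 autosomal windows, 2.08% ± 0.390 (SD, n = 4) were under 30%, and 3172 were so in every sample. The longest run of such windows, 70 kb on chromosome 2 (74650001 to 74720000), covered Evx2 and Hoxd13 to Hoxd3 at 9.39% to 14.1%. A 60 kb run on chromosome 6 (52200001 to 52260000) covered Hoxa3 to Hoxa13 at 10.4% to 15.8%, and a 50 kb run on chromosome 18 (37720001 to 37770000) covered genes of the protocadherin gamma cluster at 11.04% to 16.1%. Histone genes on chromosome 13 (23550001 to 23590000) read 10.7% to 12.4%. Of the 10 runs of 40 kb or more, 6 held no protein-coding gene, the longest of them 60 kb on chromosome 12 (114650001 to 114710000, 235 CpGs) at 17.05% to 23.5%. Genes of other kinds were not counted, so these runs are not known to be free of genes. CpGs methylated at 80% or more on a strand and 20% or less on the opposite strand made up 0.0554% ± 0.00826 (SD, n = 4) of those with 5 calls on each strand.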

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

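All tests of explanations in this part except the comparison of samples 1 and 4 with strand noise were chosen after the results were seen. Of 123 values, each compared over the 4 samples, 19 had a sample standing apart from the other 3, with a gap to its nearest neighbour over the whole range above the 95% critical value of Dixon's test; it was sample 2 in 9 cases and sample 3 in 10. Chance alone marks about 1 in 20 such groups, and the closeness of samples 1 and 4 makes such a gap more frequent.

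Several broad values had sample 2 apart. Intergenic methylation was 88.0% in sample 2 against 82.2% to 83.1% in the others, and low-CpG promoters 82.5% against 77.7% to 77.8%. The median of housekeeping promoters was 3.84% in sample 2 against 1.71% to 2.06%. Sample 2 was also apart at Gapdhs (2.48%), Cndp1 (97.8%) and Acta1 (92.2%), at the CpG-rich site of Impact (2.07%) and at the CpG-poor end of Snrpn (95.2%). Cndp1 and Acta1 were among the 10 promoters chosen for their large range, so their gaps are no separate evidence. Sample 3 was apart at Nanos2 (56.6%), Tssk1 (95.1%), Pecam1 (94.6%), Dnmt1 (95.3%), Gm10323 (2.44%, below the 5.56% to 9.09% that 0 methylated calls allow in the others, so that no gap was detectable), Zfp937 (0%, where 0 methylated calls allow up to 0.87%), Nnat (4.90%), Mcts2 (2.90%) and H19 (91.4%).

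Sample 2 was nearer the paternal pattern than the others at both Peg10 (5.02% against 35.1% to 39.6%) and Rasgrf1 (84.0% against 44.5% to 53.7%, a gap that did not pass the critical value), but at Slc38a4 it was farther from it (14.7% against 4.55% to 7.27%); sample 3 was at 21.2% at Snurf against 0.6504% to 3.29%. Cells with somatic imprints would raise all maternal regions together, but in samples 1, 3 and 4 the median of the other 14 maternal regions was 2.65%, far below the 37.2% of Peg10. In sample 3, Peg3 (0.675%), Airn (3.63%), Zrsr1 (2.59%) and Kcnq1ot1 (4.47%) were at their lowest. Nnat (4.90%), Mcts2 (2.90%), Nespas (1.70%) and Peg13 (1.91%) were at their highest there, and paternal H19 at its lowest (91.4%). A small share of such cells in sample 3 is therefore not excluded. Reads misplaced from a similar sequence stay open, as the regions were chosen for their ranges, the smallest being 20.5 points. Incomplete erasure or setting of single imprints in the founder cells of a sample stays open too; no biological explanation was tested, as the labels name no difference between the samples.

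Samples 1 and 4 were closer to each other than any other pair. A single library deposited 2 times was taken to differ in coverage only by the clustering of calls on reads. Such clustering was taken not to grow with window size. The coverage chi-square per degree of freedom was 1.54 times higher in 1 Mb than in 10 kb windows (2.76 to 3.49 times in the other pairs). The ratio within a single library was not measured, so this value does not exclude a single library. At CpGs between 20% and 80%, the methylation chi-square per CpG between them was 1.45, which is 1.15 times the mean of 1.26 between strands within a sample, and the other pairs gave 10.8 to 11.2. The ratio is above the 1.1 set beforehand as the limit for libraries from a single population of cells, but that limit was wrong, as strands of a library hold no variation between libraries. A single library, a single population of cells and separate cultures of a shared line all remain open, since the labels do not say what the sample numbers stand for.

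Mitochondrial CpGs, not used in the comparisons, had 27.9% ± 0.289 methylated calls (SD, n = 4), at 27.6% to 28.3% in the samples. Cytosines left unconverted in all DNA would show equally in nuclear promoters, but high-CpG promoter windows read 2.39%. Reads of nuclear copies of mitochondrial DNA would need about 36.5 copies per CpG at the median nuclear depth, and as the number of copies is not in the tables this stays open, as does poor conversion of mitochondrial DNA alone. The level differed between sites, from 5.26% to 63.7% at CpGs with 1000 or more calls, in the same way in all samples (Pearson's r 0.991 to 0.995 over 191 CpGs of the 6 pairs, across sites). No biological explanation was tested.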

How the results depend on the processing

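Of 275 alternative values of 30 main results, 250 kept their direction, side of the threshold or size, and 19 results did so under every alternative run, among them the genome-wide, feature and imprint differences. For the genome-wide level, leaving out 1 of 4 samples cannot move the mean by 1 SD, so those alternatives could not fail. Alternatives that restrict genes to a clear end, use added CpG-rich imprint sites, count overlapping windows or samples 1 and 4 once, keep autosomes only, or leave out a sample from the correlation, and all those for single genes and regions, were chosen after seeing the data. Where a value moved, the cause was not tested unless the setting itself sets the size.

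With clear ends only, windows at 80% or more numbered 1068, the median of spermatid genes fell below random lists (6.77%) and the receptor median of 83.1% was no longer called (adjusted p = 0.895). For receptors, no matching put the same median of 86.5% above random lists, and the mean of 77.4% lay slightly above them. With 500 bp windows pluripotency genes (6.91%) and lineage transcription factors (1.75%) passed the threshold (both adjusted p = 0.0336; over their other alternatives neither passed), as did fibroblast, endothelial and blood markers (76.4%, adjusted p = 0.0389) without matching.

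Promoters differing between samples numbered 869 on the logit scale, 3041 with no minimum range, 900 with 30 points, 851 to 1470 when a sample was left out, and 622 of 13682 with a clear end. Counting overlapping windows once gave 1478. The 10 kb windows numbered 133215 and 7597 with those ranges, and 6651 to 20241 with a sample left out. The share of windows under 30% was 0.685% and 7.08% at thresholds of 20% and 50%, and 4.18% and 0.476% in 2 and 50 kb windows. Mean correlation was 0.867 in high-CpG promoters and 0.812 outside the extremes. Opposed strands made up 0.0113% with 10 calls per strand and 0.00364% with bounds of 0% and 100%. Of 444 values for single genes and regions, 423 moved by less than 1 SD. Leaving out 1 of 4 samples cannot move their mean by 1 SD, so those values could only count as unmoved. The 21 that moved all came from 500 bp windows, where Nanos2 read 92.0% and Dppa3 29.5%. At this depth, 2.0% of shifts of 20 points were recovered in simulated promoters; 2 times the read minimum gave 1487 differing promoters.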

Other observations

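The tests in this part were set down before their results were seen, and concern patterns noticed in these data. Olfactory and vomeronasal receptor genes were more often among the promoters that differed between samples than other low-CpG promoters were: 263 of 1103 receptor windows (23.8%) against 670 of 5018 others (13.4%; Fisher's exact test p = 6.53e-17, odds ratio 2.03). Receptor genes lie in clusters and are not independent, so this p is too small. The differing 10 kb windows lay side by side: of those with a tested next window, 37.9% were followed by another, against 8.51% of all windows, 4.46 times as often. There were 13451 runs, 136 of them 100 kb or longer.

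Of the differing windows, 18.1% overlapped a protein-coding gene, against 46.1% of all tested windows, a ratio of 0.392, with a lower share on 20 of 20 chromosomes. Exceptions exist, such as the run on chromosome 16 with 29 genes. These values fit a hypothesis that the samples differ in broad domains poor in protein-coding genes, with some receptor clusters among them. Genes of other kinds were not counted. In the 15 longest runs of differing windows, samples 1 and 4 were at 22.4% to 54.8% and samples 2 and 3 at 57.7% to 88.6%. In the 11 of these runs without a protein-coding gene, the ranges were 34.3% to 51.5% and 67.3% to 88.6%. Replication timing or lamina maps, which would test whether these are late-replicating domains, were not used here.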
